A study of Rattus norvegicus with 6 samples.

How the data were processed

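RNA from 6 cultures of neonatal rat ventricular myocytes was analysed, 3 given an adenovirus with GFP and 3 given an adenovirus with Tbx18 followed by an internal ribosome entry site and GFP. Per the labels' protocols, cells came from Sprague Dawley rats at postnatal day 1 to 3, were plated on fibronectin in M199-based medium with 10% serum for the first 2 days and 2% from day 3, were transduced on the day of isolation and were harvested on day 4 after gene transfer. Libraries were made from 100 ng of total RNA with a stranded mRNA kit and read as 101 bp pairs. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.4.0g1, HTSeq and DESeq2 1.10.1 without their roles. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed and values of paralogous or overlapping genes are less certain.

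The deposited signal is, by its name, a table of DESeq2-normalized counts. In these the authors divided the gene read counts of each library by 1 size factor. The column headers of every library carry the words unpace and Control. The deposited signal held 17089 genes, named by symbol, of which 2912 were at 0 in every library. Every value was a whole multiple of a column's smallest step within a tolerance of 0.01, so read counts were recovered and gave 17074483 to 19800300 reads per library. The size factors differed from median-of-ratios factors recomputed on these libraries by a ratio of 0.956 to 0.967. No intervals on counting error are given, since the spread between libraries exceeds it.

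Group differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2 of the normalized count plus 1, for the 11230 genes with a mean of at least 10 over the 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no block. Before the data were examined, 27 gene lists were fixed with 656 symbols, of which 57 were not matched. The 25 lists with at least 5 tested members were tested with camera in limma, two-sided, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Each list's counts are also given with p-values adjusted over the list alone; where the report gives no such count it equals the count over all genes tested.

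Named genes were set by a rule fixed before the data were examined. It took Tbx18, and the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 100, groups that do not overlap and a proper symbol. It took the 6 called members with the largest change from the sinoatrial, pacemaker and ventricular lists and the 3 largest from every other list. It also took Hcn4, Tbx3, Shox2, Isl1, Gja1, Kcnj2, Nkx2-5, Nppa, Cdh1 and Snai1 whatever their result, and a further gene that is not reported here. Members named because they moved against their list were chosen after their values were seen, as were B2m, Cacna1g, Cacna1h, Cd68, Irf7, Isg15, Myh6, Myl2 and Wt1. For a gene at 0 in all libraries of a group, the fold is a lower bound against 3 reads per library.

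Alternatives covered other scalings, pseudocounts, filters, limma settings, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a replicate block, a fold threshold and leaving out each library; scaling to equal recovered reads was added after the data were seen. The tests were tried on simulated counts of 11191 genes. There limma recovered 65.7% of 1.5-fold changes, 94.0% of 2-fold and 100% of 4-fold changes, with 4 false calls among 176. The simulation changed only 67, 67 and 65 genes at these folds, up or down at random. It used known size factors and the same spread in both groups. The data had 46.0% of tested genes called and a median SD of 0.17 within GFP against 0.10 within Tbx18. These rates therefore need not hold for the data. Camera gave an unadjusted p under 0.05 for 0 of 100 unchanged lists. The simulated genes were drawn independently and those lists at random, so this does not test lists whose genes vary together. In the data the estimated correlations of the lists ran from -0.08 for epicardial to 0.85 for cell cycle genes.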

Results

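The study asked how the transcriptome of ventricular heart muscle cells changes when they are made to express Tbx18, a T-box transcription factor of the embryonic sinus node region, in order to obtain pacemaker-like cells. Neonatal rat ventricular myocytes, primary cultures prepared from the ventricles of Sprague Dawley rats at postnatal day 1 to 3, received on the day of isolation an adenovirus carrying either GFP or Tbx18 followed by GFP, and RNA was collected on day 4 after gene transfer. There were 3 libraries per group, called GFP and Tbx18 below. The 3 GFP libraries held 18934232, 17460507 and 18200875 gene-assigned reads and the 3 Tbx18 libraries 18765654, 17074483 and 19800300, as recovered from the deposited normalized counts. The first principal component of the log2 values held 78.3% of the variance and separated the groups. The GFP libraries differed more among themselves, with a median SD of the log2 values of 0.17 against 0.10 within Tbx18. The limma tests took 1 variance per gene over both groups. The labels do not say whether replicates were separate isolations, so the p-values given here measure only the spread between these libraries, which may be technical. Values below are mean normalized counts ± SD over 3 libraries, and folds are ratios of these means.

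Tbx18 itself was read at 312, 268 and 296 normalized counts in the GFP libraries and at 6004, 6236 and 5937 in the Tbx18 libraries, so every library matched its label. The rise was 20.8-fold, from 292 ± 22.1 to 6059 ± 157 (log2 fold change 4.37, SE 0.09, limma adjusted p = 5.98e-09). The species of the transgene is not stated in the labels, so vector reads may have been counted only in part on the rat gene, and vector and endogenous transcripts cannot be separated. Of 11230 genes tested, 2525 were higher and 2639 lower in Tbx18 than in GFP at an adjusted p under 0.05, together 46.0% of the genes tested. A change of at least 2-fold was reached by 903 of the higher and 474 of the lower genes. The groups did not overlap for 5100 of the 5164 called genes, and for 57.2% of all genes tested against 10% by chance. The deposited totals differed between the groups, and the 10 most abundant genes took 10.9 to 11.1% of them in GFP and 8.20 to 8.92% in Tbx18. With libraries scaled to equal recovered reads, a choice made after seeing those totals, the median log2 fold change of all genes was 0.27 in place of 0.01 and the split was 4770 higher and 1351 lower; with upper-quartile scaling it was 0.18, with 3894 higher and 1699 lower.

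**Figure D1:**
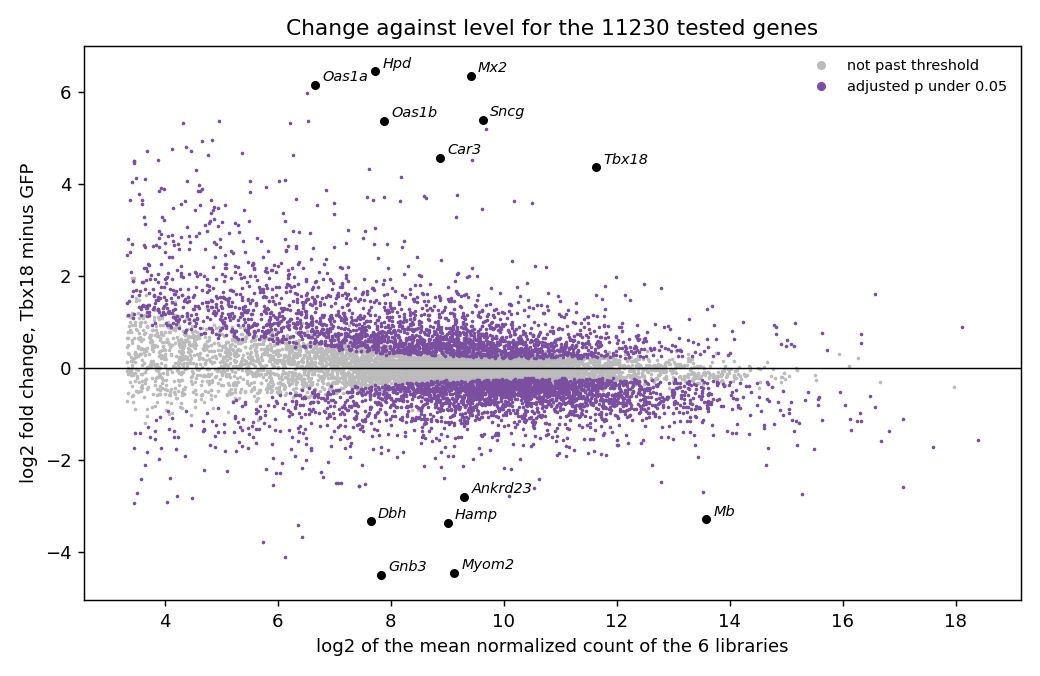
Each point is 1 of the 11230 tested genes, with the log2 of its mean normalized count over the 6 libraries on the x axis and its log2 fold change, Tbx18 minus GFP, on the y axis. Genes with an adjusted p under 0.05 are purple, and the black points are Tbx18 at 4.37 and the 12 genes named for the most extreme changes, from Hpd at 6.46 to Gnb3 at -4.49.

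The largest rises among genes with a mean of at least 100 normalized counts were those of Hpd, an enzyme of tyrosine breakdown, from 4.43 ± 3.11 to 418 ± 55.2, and Mx2, an interferon-induced GTPase, from 14.2 ± 1.73 to 1349 ± 590.4. Sncg, which encodes gamma-synuclein, rose 43.3-fold to 1544 ± 160.2, and Car3, a carbonic anhydrase of muscle and fat, rose 22.8-fold to 900.4 ± 166. The oligoadenylate synthetase genes Oas1a and Oas1b rose to 199 ± 84.3 and 460.1 ± 154, from 2.19 ± 2.13 and 9.61 ± 1.35, the log2 fold change of Oas1a, 6.17, being 5.48 without GFP replicate 2. At the other end, Gnb3, a G protein beta subunit, fell 23.8-fold from 437 ± 163 to 18.4 ± 7.195, and Myom2, a protein of the sarcomeric M-band, fell 22.5-fold from 1069 ± 217 to 47.6 ± 2.56. Hamp, which encodes hepcidin, fell 12.7-fold, with GFP values that ranged from 415 to 1838, and its log2 fold change of -3.35 was -2.73 without GFP replicate 3. Dbh, the enzyme that makes noradrenaline, fell 9.95-fold, Mb, myoglobin, 9.86-fold from 22320.5 ± 6494, and Ankrd23, a titin-binding protein, 7.003-fold. The log2 fold changes of these 12 genes lay between -4.49 and 6.46, with limma adjusted p-values from 4.20e-08 to 0.000244. Oas1a and Oas1b, like Mx1 and Mx2, are close paralogs whose reads the counting could have split.

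Among pacemaker genes, Hcn4, the main channel of the pacemaker current in the sinus node, rose 6.36-fold from 79.8 ± 15.9 to 507 ± 117 (log2 fold change 2.65, SE 0.20, limma adjusted p = 1.38e-05). Hcn2, the other abundant channel of that family, fell 2.09-fold from 1292 ± 163 to 617 ± 71.7, and Kcnj5, a subunit of the acetylcholine-gated potassium channel, fell 2.42-fold. The sodium-permeable channel gene Trpm4 was called higher by 0.48 and Trpc1 lower by a log2 fold change of -0.37. Trpm4 was not called without Tbx18 replicate 1 or without Tbx18 replicate 3 (adjusted p from 0.00111 to 0.0579 over its alternatives). Trpc1 was not called without GFP replicate 3, without any 1 of the Tbx18 libraries, with upper-quartile scaling or with equal recovered reads (adjusted p from 0.0170 to 0.487 over its alternatives). Of 16 tested members of the pacemaker channel list, 2 rose, 3 fell and 11 did not pass the test, among them the calcium channel genes Cacna1g with 2079 and 1971 counts and Cacna1h with 2066 and 2439 counts in GFP and Tbx18. The list was not called (camera adjusted p = 0.903), and its median log2 fold change was 0.06, or -0.05 after quantile normalization. With upper-quartile scaling 5 members rose and 2 fell, with equal recovered reads 6 and 2, after quantile normalization 4 and 4, with no filter 4 and 3, without GFP replicate 1 6 and 3, and without Tbx18 replicate 1 or Tbx18 replicate 3 1 and 2. The median was 0.21 without GFP replicate 1, 0.00193 without GFP replicate 3 and 0.0236 without Tbx18 replicate 1.

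Sinoatrial node transcription factors and markers moved both ways, with 7 of 18 tested members higher and 7 lower. Cpne5, a copine, rose from 4.71 ± 4.96 to 44.4 ± 6.06, Igfbp5, an insulin-like growth factor binding protein, rose 6.61-fold from 55.5 ± 50.3 to 367 ± 102, and Nr2f2, a nuclear receptor of atrial and venous identity, rose 2.55-fold. The GFP libraries differed for Igfbp5, at 35.1, 18.5 and 113 counts, and its log2 fold change of 3.06 was 3.76 without GFP replicate 3; that of Cpne5, 3.55, was 4.30 without GFP replicate 2 and 2.58 without GFP replicate 3. Tbx3, a T-box repressor of the working myocardial programme, went from 41.9 ± 11.5 to 71.5 ± 7.46 (log2 fold change 0.79, limma adjusted p = 0.0254), and Shox2, a homeobox gene of the sinus node, from 6.79 ± 2.81 to 18.3 ± 3.39 (1.36, adjusted p = 0.0214). Both calls rested on few counts. The Tbx3 call was lost without GFP replicate 3, without any 1 of the Tbx18 libraries and after quantile normalization (adjusted p from 0.00656 to 0.239 over its alternatives), and the Shox2 call without Tbx18 replicate 1, without Tbx18 replicate 3 and after quantile normalization (adjusted p from 0.00917 to 0.315). Isl1, a transcription factor of the sinus node, was read at 1.86 and 1.95 counts in GFP and Tbx18 and was not tested. Smoc2 fell 4.87-fold and Rgs6, a regulator of G protein signalling, 2.64-fold. As a whole the list was not called (camera adjusted p = 0.903). With upper-quartile scaling and with equal recovered reads 10 members rose and 6 fell, and after quantile normalization 3 and 7. Without Tbx18 replicate 1 or Tbx18 replicate 2 the counts were 4 and 6, and without Tbx18 replicate 3 they were 3 and 6. Its median log2 fold change was 0.29, camera put it higher and fry lower, and with a minimum mean of 50 counts the median was -0.30.

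**Figure D2:**
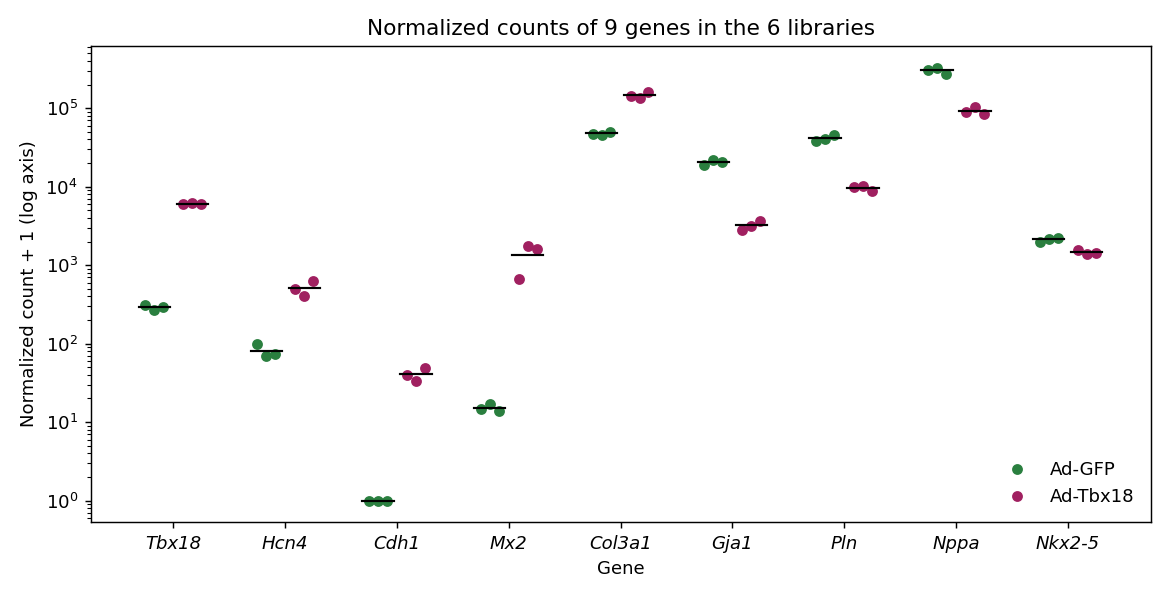
Normalized counts plus 1, on a log axis, of 9 genes in each library, with GFP libraries in green, Tbx18 libraries in red and black bars at the group means. Tbx18, Hcn4, Cdh1, Mx2 and Col3a1 lie higher in all 3 Tbx18 libraries, Gja1, Pln, Nppa and Nkx2-5 lower, and Cdh1 was 0 in the 3 GFP libraries.

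Genes of the working ventricular myocardium were lower. Gja1, the gap junction protein that couples working myocytes, fell 6.39-fold from 20488 ± 1518 to 3206 ± 432 (log2 fold change -2.68, SE 0.11, limma adjusted p = 1.27e-06). The natriuretic peptide genes Nppa and Nppb fell 3.28-fold and 6.70-fold, Irx4, a ventricular homeobox gene, fell 3.30-fold, Kcnj2, a channel of the inward rectifier current that holds the resting potential, fell 2.06-fold, and the cardiac transcription factor Nkx2-5 fell 1.45-fold, from 2124 ± 147 to 1462 ± 88.3. Of 20 tested members of the list, 14 fell, 1 rose, namely Kcnj12, another inward rectifier gene, and 5 did not pass the test, among them the regulatory light chain gene Myl2 with 27229 and 19814 counts. Adjusted over the list alone, 16 were lower. The list was called lower (camera adjusted p = 5.75e-07, median log2 fold change -1.05); adjusted p = 0.113 with an estimated correlation.

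The contractile apparatus followed the same direction. Of 29 tested sarcomere and Z-disc genes, 24 fell, 26 when adjusted over the list alone, with a median log2 fold change of -1.06. Besides Myom2, Myh7, the slow beta-myosin heavy chain, fell 5.94-fold from 235206 ± 17340 to 39582 ± 2848, and Acta1, skeletal alpha-actin, fell 3.44-fold. Myh6, the alpha heavy chain, was at 291846 and 219223 counts and did not pass the test. The atrial and fetal light chain gene Myl4 was the member called higher, by 0.45, and 0 members were called higher without Tbx18 replicate 1 or Tbx18 replicate 2. It was called lower (camera adjusted p = 5.51e-12); adjusted p = 0.244 with an estimated correlation. Myosin and actin genes have close paralogs among which the counting could have split reads.

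Calcium handling genes and genes of the cell contacts between myocytes were lower as well. Of 21 calcium handling genes, 11 fell and 2 rose, among them the inositol trisphosphate receptor gene Itpr1. Pln, phospholamban, the inhibitor of the sarcoplasmic reticulum calcium pump, fell 4.27-fold from 41272 ± 4377 to 9673 ± 760.3, Sln, sarcolipin, fell 5.57-fold, and Cacnb2, a calcium channel beta subunit, fell 2.30-fold. The list was called lower (camera adjusted p = 0.00460, median log2 fold change -0.45), and camera adjusted p was 0.174 with an estimated correlation. Its median was -0.19 with equal recovered reads, where 8 fell and 3 rose, -0.28 with upper-quartile scaling and -0.27 after quantile normalization. With the preset correlation it stayed called under each of these scalings. Of 16 intercalated disc and gap junction genes, 11 fell and 2 were called higher, Gja5 and Jup, with 3 higher when adjusted over the list alone. When any 1 of the Tbx18 libraries was left out 0 members were called higher, and without GFP replicate 2 there was 1. Pkp2, the desmosomal plakophilin, fell 3.16-fold and Ctnna1, alpha-catenin, 2.34-fold. This list was also called lower (camera adjusted p = 0.000391, median log2 fold change -0.65); adjusted p = 0.174 with an estimated correlation. Markers of stromal cells, given below, moved the other way in the same libraries, with a median log2 fold change of 0.86 for the fibroblast list.

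Potassium channel genes split by member. Of 21 tested, 3 rose and 7 fell: Kcne4, an accessory subunit, rose 4.21-fold to 101 ± 21.5, and Kcnk2, a stretch-sensitive background channel, 3.67-fold to 336 ± 39.1, while Abcc9, the sulfonylurea receptor of cardiac potassium channels, fell 2.86-fold from 3280.3 ± 678. The list was not called (camera adjusted p = 0.629), its median log2 fold change being -0.11, its mean 0.01 and the sign of its test lower; the median was 0.06 with upper-quartile scaling, where 4 rose and 4 fell, 0.15 with equal recovered reads, where 4 rose and 3 fell, 0.05 without GFP replicate 3 and -0.20 without GFP replicate 2. Without GFP replicate 1 5 rose and 8 fell. Of 32 genes of cAMP and autonomic signalling, 8 rose and 12 fell, 13 when adjusted over the list alone. Adra1b, an alpha-adrenergic receptor, fell 3.85-fold from 247 ± 28.1 to 64.3 ± 10.6, and the phosphodiesterase genes Pde1a and Pde5a rose 2.65-fold and 2.07-fold. That list was not called (camera adjusted p = 0.629), with a median of 0.02, or -0.03 after quantile normalization, a mean of -0.05 and a test in the lower direction. With upper-quartile scaling 12 rose and 10 fell (median 0.19), and with equal recovered reads 15 and 6 (median 0.28). With 1 library left out the median ran from -0.11 without GFP replicate 2 to 0.10 without GFP replicate 3, and 5 rose and 11 fell without Tbx18 replicate 3.

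Energy metabolism genes were lower almost throughout. None of the 46 tested genes of oxidative phosphorylation and the TCA cycle rose and 44 fell, 45 when adjusted over the list alone, with a median log2 fold change of -0.71. Cox6a2, the muscle form of a cytochrome oxidase subunit, fell 2.31-fold from 39603 ± 3265, Ppargc1b, a coactivator of mitochondrial biogenesis, fell 2.33-fold, and Ndufa4 fell 2.08-fold. The call was strong with the preset correlation (camera adjusted p = 7.45e-15); adjusted p = 0.292 with an estimated correlation. Of 26 fatty acid oxidation genes, 22 fell, 23 when adjusted over the list alone, among them Fabp3, the heart fatty acid binding protein, 3.85-fold, Pdk4, a kinase that restrains pyruvate oxidation, 3.57-fold, and Acsl1, which activates long-chain fatty acids, 2.98-fold. The median was -0.66 (camera adjusted p = 1.34e-08); adjusted p = 0.292 with an estimated correlation. Of 26 glycolysis genes, 23 fell, including the glucose transporter genes Slc2a4, 3.24-fold, and Slc2a1, 3.07-fold, and the pyruvate dehydrogenase kinase gene Pdk1, 3.57-fold. The enolase gene Eno3 rose by 0.67, and adjusted over the list alone 2 genes were higher and 23 lower. The median was -0.97 (camera adjusted p = 5.55e-10); adjusted p = 0.276 with an estimated correlation. With equal recovered reads the medians of these 3 lists were -0.45, -0.39 and -0.70 against 0.27 for all genes.

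Matrix and stromal genes were higher. Of 24 fibroblast and matrix genes, 17 rose: Col3a1, a fibrillar collagen, 3.08-fold from 47780 ± 2276 to 147143 ± 13398, Postn, periostin, 2.52-fold, and Pdgfra, the growth factor receptor of fibroblasts, 2.52-fold. Ctgf, a matricellular growth factor, and Tnc, tenascin C, were the 2 members that fell, by 1.11 and by 0.32 on the log2 scale, and adjusted over the list alone 3 were lower; 1 was called lower without GFP replicate 2, Tbx18 replicate 1 or Tbx18 replicate 2 and with upper-quartile, quantile and equal-read scaling. As a list these genes were called higher (camera adjusted p = 1.62e-05, median log2 fold change 0.86); adjusted p = 0.292 with an estimated correlation. Of 16 smooth muscle and pericyte genes, 10 rose and 2 fell, the rises including Sncg, Itga8, an integrin subunit, 3.40-fold, and Pdgfrb 2.80-fold, while Myocd, the cofactor of smooth muscle transcription, fell by 1.24 and Cnn1, calponin, by 0.93. It was called higher (camera adjusted p = 0.00141, median 0.70); adjusted p = 0.471 with an estimated correlation. Of 16 endothelial genes, 9 rose, among them Erg, Cldn5 and Tek with 4.01-fold, 2.73-fold and 2.69-fold, and Kdr fell by 0.56, with 0 members called lower with equal recovered reads. This call (camera adjusted p = 0.00880, median 0.56) did not hold with equal recovered reads, where adjusted p = 0.0889, by fry, where adjusted p = 0.0822, or in camera, where adjusted p = 0.597 with an estimated correlation; over its alternatives adjusted p ran from 0.00141 to 0.597. The median was 0.36 without GFP replicate 2, and the GFP libraries deviated from their group means by medians of 0.35, -0.37 and 0.09.

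Epicardial and mesothelial genes and genes of the epithelial-mesenchymal transition were higher too. Krt8, a keratin of simple epithelia, rose 11.9-fold from 223 ± 57.2 to 2662 ± 353 (log2 fold change 3.59, SE 0.17, limma adjusted p = 2.27e-06), and Tcf21, a transcription factor of epicardium and fibroblast precursors, 3.85-fold. Of 12 tested epicardial and mesothelial genes, 10 rose, Tbx18 itself being among them, Gpm6a fell by 0.66, and Wt1 did not pass the test at 108 and 137 counts. The list was called higher (camera adjusted p = 4.09e-05, median 1.52), and camera adjusted p was 0.126 with an estimated correlation. Both tests counted Tbx18, the gene carried by the vector, and neither was run without it. The median was 1.48 without Tbx18. Of 25 genes of the epithelial-mesenchymal transition, 13 rose and 2 fell, with 14 and 3 when adjusted over the list alone. Snai1 and Snai2, repressors of epithelial genes, rose 2.22-fold to 1026 ± 30.0 and 3.09-fold to 229 ± 22.4, and Mmp14, a membrane metalloproteinase, rose 3.04-fold. Cdh1, the epithelial cadherin that is usually lost in that transition, was at 0 in all GFP libraries and at 39.9 ± 7.82 in Tbx18, at least 11.6-fold higher against a floor of 3 reads per library. Among the members called lower was Ncam1, which fell by 0.56; 1 member was called lower without Tbx18 replicate 1 or Tbx18 replicate 2 and with upper-quartile, quantile and equal-read scaling, and 4 without GFP replicate 1. Together these genes were called higher (camera adjusted p = 0.00707, median 0.39, also with Cdh1 at its bound), and camera adjusted p was 0.292 with an estimated correlation. The 13 that rose include Cdh1, and the test was not run without it. The call therefore gives the direction of the listed genes, not that of the transition.

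Markers of leukocytes, Schwann cells and red cells, which a ventricular preparation can also contain, were not called as lists by camera. Of 18 macrophage and leukocyte genes, 4 were called higher, and 0 when adjusted over the list alone: Cd74, the MHC class II invariant chain, 2.14-fold, Mrc1 1.66-fold, Csf1r, the macrophage growth factor receptor, 1.68-fold, and Cd68. The Cd74 call was lost without GFP replicate 2 or any 1 Tbx18 library, after quantile normalization, without the intensity trend and with edgeR (adjusted p from 0.00275 to 0.114 over its alternatives). Its log2 fold change of 1.39 was 0.77 without GFP replicate 1 and 1.98 without GFP replicate 3. The Mrc1 call was lost without GFP replicate 3, Tbx18 replicate 2 or Tbx18 replicate 3, after quantile normalization and without the trend (0.00435 to 0.121), and the Csf1r call without Tbx18 replicate 3 (0.00162 to 0.0553). The leukocyte list was not called (camera adjusted p = 0.130, median 0.30), but it was without GFP replicate 2, where the median was 0.62 and adjusted p = 0.00371, and without Tbx18 replicate 1, where these were 0.42 and 0.0444. Its median was 0.12 without GFP replicate 1, 0.18 without Tbx18 replicate 3, with 0 genes called, and 0.0224 after quantile normalization; 2 genes were called without GFP replicate 3 and 1 without Tbx18 replicate 2. Over its alternatives adjusted p ran from 0.00371 to 0.865. Of 8 Schwann and neural genes, 5 rose, with Erbb3 at 4.44-fold and S100b at 2.15-fold from 11.6 ± 2.83 counts, and Dbh fell. Without Tbx18 replicate 3 only 3 rose. Camera did not call that list (adjusted p = 0.119) but fry did (adjusted p = 0.00431; 0.00431 to 0.552 over its alternatives), and the S100b call was lost without Tbx18 replicate 1, without Tbx18 replicate 3, after quantile normalization and with DESeq2 (adjusted p from 0.00420 to 0.388 over its alternatives). Only 3 erythroid genes passed the filter, too few for a test, and of these Slc4a1, the red cell anion exchanger, rose from 3.72 ± 2.18 to 31.1 ± 4.27. No mitochondrially encoded gene was matched in the table, and that list was not analysed here.

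Interferon-response genes formed the list with the highest median. All 25 tested members rose, also adjusted over the list alone, with a median log2 fold change of 1.82. Mx1 rose from 3.04 ± 0.51 to 182 ± 89.0 beside the rises of Mx2 and Oas1a, Irf7, a transcription factor of the interferon response, from 74.2 to 1075, and Isg15, a ubiquitin-like antiviral protein, from 29.9 to 444, while B2m, which was already abundant, rose by 0.52 from 6580 to 9456. The list was called higher (camera adjusted p = 3.71e-13); adjusted p = 0.276 with an estimated correlation. After quantile normalization 24 of the 25 rose. Tbx18 replicate 1 lay below the other Tbx18 libraries, its members deviating from their group means by a median of -0.42 (Mx2 at 672 against 1754 and 1622), at a like level of Tbx18. Inflammatory cytokine and NF-kB genes moved less evenly, with 5 of 15 higher and 2 lower: the alarmin gene Il33 rose 4.15-fold, the adhesion molecule gene Vcam1 2.495-fold, and Ptgs2, the inducible cyclooxygenase, fell 3.06-fold. Camera did not call that list (adjusted p = 0.130, median 0.32) but fry did (adjusted p = 0.0182; 0.0182 to 0.597 over its alternatives). The median was 0.21 without GFP replicate 1, 0.20 without GFP replicate 3 and 0.13 with no filter on low values. When any library other than GFP replicate 1 was left out 1 member was called lower. With equal recovered reads 8 rose and 1 fell (median 0.58), with upper-quartile scaling 6 and 1 (0.49), and after quantile normalization 6 and 3 (0.21).

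Endoplasmic reticulum stress, p53 and cell cycle lists were not called by camera or fry. Of 22 endoplasmic reticulum stress genes, 6 rose and 7 fell, with Atf3, a stress-induced transcription factor, 8.14-fold lower, Asns, asparagine synthetase, 2.12-fold lower and Pdia4, a protein disulfide isomerase, 1.66-fold higher; Atf3 ranged from 658 to 4954 among the GFP libraries, and its log2 fold change of -2.60 was -3.39 without GFP replicate 1 and -1.93 without GFP replicate 3. Of 20 genes of the p53 and apoptosis list, 3 rose and 3 fell, among them Gadd45a, a growth arrest gene, 3.76-fold lower, Fas, a death receptor, 2.42-fold higher and Casp8 2.04-fold higher. Both lists had a camera adjusted p = 0.903, with medians of -0.06 and 0.07 and means of -0.16 and -0.02. Camera put the first lower and the other higher, fry the reverse. With upper-quartile scaling 8 stress genes rose and 3 fell (median 0.12), after quantile normalization 8 and 6 (0.11), and with equal recovered reads 11 and 3 (0.21); the counts were 4 and 4 without Tbx18 replicate 1 and 4 and 3 without Tbx18 replicate 3. Of the p53 list 8 rose and 3 fell with upper-quartile scaling (median 0.24), 6 and 5 after quantile normalization (0.11), 12 and 3 with equal recovered reads (0.33), and 5 and 4 without GFP replicate 2. Of 33 cell cycle genes, 2 were called higher, the replication helicase genes Mcm7 and Mcm2 by 0.54 and 0.39, and 0 when adjusted over the list alone. The Mcm2 call was lost without each library except GFP replicate 1 and without the intensity trend, and the Mcm7 call without Tbx18 replicate 2 (highest adjusted p-values 0.0987 and 0.0606). The cell cycle list was not called (camera adjusted p = 0.629, median 0.01), but it was called higher without GFP replicate 1, where 16 genes rose, the median was 0.38 and adjusted p = 0.000211, and its median was -0.26, with 7 genes lower, without GFP replicate 3; adjusted p over its alternatives ran from 0.000211 to 0.954. In the GFP libraries its members deviated from their group means by medians of 0.69, -0.12 and -0.65.

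Of 22 Wnt signalling genes, 14 rose and 5 fell. Frzb and Sfrp2, secreted inhibitors of Wnt, rose 3.45-fold and 2.66-fold, and Wif1, another such inhibitor, fell 3.08-fold from 238 ± 9.73 to 77.2 ± 7.15; the Sfrp2 call was lost without Tbx18 replicate 3 and after quantile normalization (highest adjusted p 0.0567). The list was not called (camera adjusted p = 0.0793, median 0.47), but was with no filter on low values, where adjusted p = 0.0459 (0.0459 to 0.542 over its alternatives), and without Tbx18 replicate 3 9 genes rose and 4 fell. Of 29 Notch, BMP and TGF-beta genes, 12 rose and 5 fell (median 0.28). The ligand gene Jag1 rose 3.50-fold and the receptor gene Notch1 2.19-fold, and the coreceptor gene Tgfbr3 fell 2.19-fold. With equal recovered reads 17 rose and 3 fell (median 0.54), with upper-quartile scaling 14 and 5 (0.45), and after quantile normalization 12 and 5 (0.16). Camera did not call the list (adjusted p = 0.106) but fry did (adjusted p = 0.0325; 0.0325 to 0.542 over its alternatives).

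**Figure D3:**
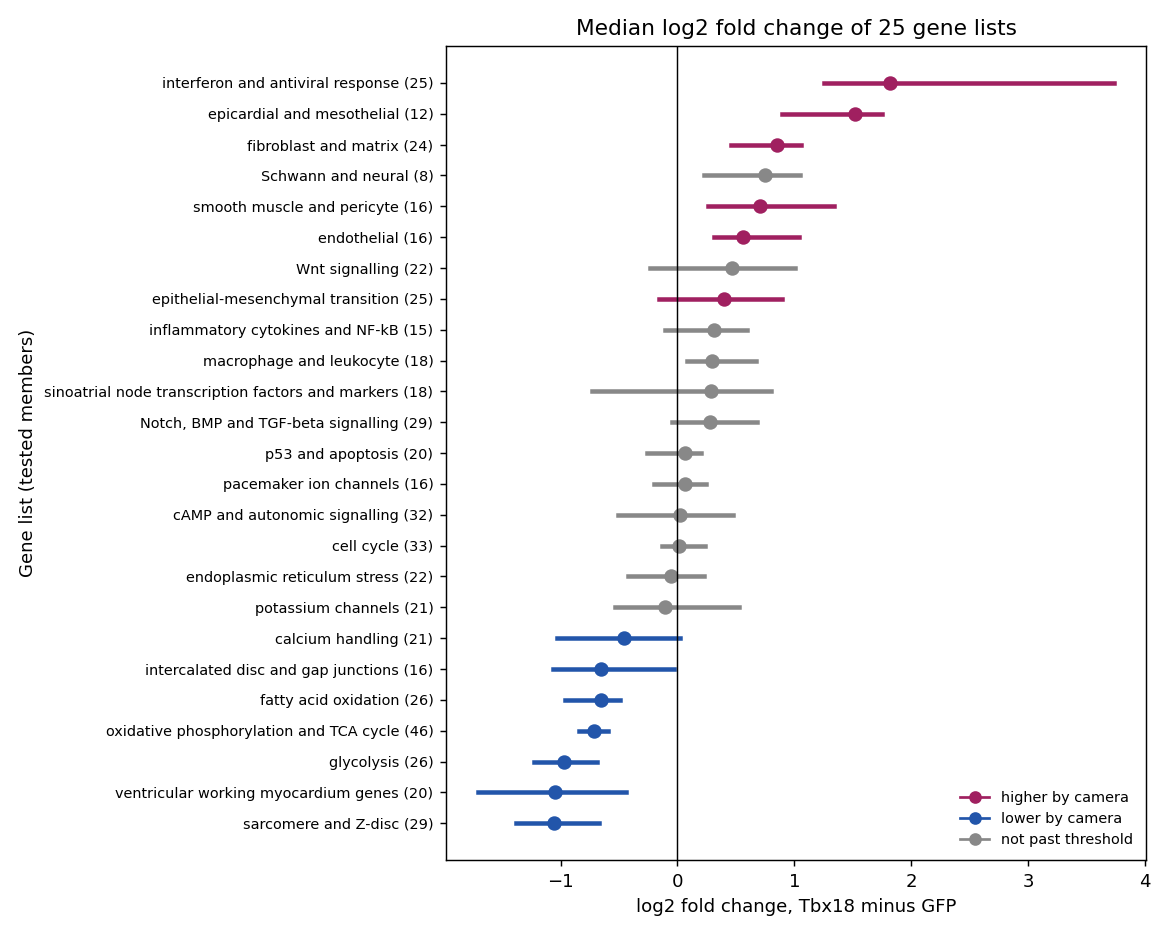
Points are the median log2 fold change, Tbx18 minus GFP, of the tested members of 25 gene lists, with bars from the first to the third quartile and the number of tested members in brackets. The 6 lists called higher and the 7 called lower with the preset correlation are coloured, from interferon genes at 1.82 to sarcomere genes at -1.06, and with an estimated correlation 0 lists were called.

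In all, 6 of 25 lists were called higher and 7 lower with the preset inter-gene correlation of 0.01. Camera with a correlation estimated from these libraries called 0 (5 lists at an unadjusted p under 0.05). That setting also changes the degrees of freedom, which then come from the few libraries and not from the genes. The ventricular, epicardial and calcium handling lists had estimates below the preset, at -0.018, -0.076 and -0.0075. Correlated genes therefore do not account for the loss of those calls. Fry called 15 lists. It tests whether the members move on balance without comparing them with other genes.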

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

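Scaling to equal recovered reads and the groups of genes chosen afterwards were added after the data were seen; the other alternatives were fixed before. Of 92 named genes, 81 kept their direction and their side of the threshold under every alternative run on them, 0 reversed, and 11 lost a call under at least 1. Most were named for large changes, so these counts do not describe all called genes. Of all called genes, 75.1% stayed called in the same direction with equal recovered reads, 81.8% with upper-quartile scaling and 81.5% after quantile normalization. With 1 library left out this share ran from 76.4% without Tbx18 replicate 1 to 95.6% without GFP replicate 1. With edgeR it was 98.5% and with DESeq2 96.4%. The split of called genes was 3894 higher and 1699 lower with upper-quartile scaling and 4770 higher and 1351 lower with equal recovered reads, whose construction shifts all genes by a median of 0.18 and 0.27. With a fold of at least 2 required it was 903 and 474, the stricter criterion being the cause. Leaving out 1 library gave 1905 to 2870 higher and 2056 to 2967 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, with 5 at an unadjusted p under 0.05.

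The fixed lists whose test or median changed direction had not passed the threshold in the first place, and the cause was not tested. The settings named below are those in which the test changed direction, also where the median kept its sign. Ranges with 1 library left out cover every library. Fry, which gives no median, changed the direction of the test for the sinoatrial, endoplasmic reticulum stress and p53 lists. For the sinoatrial list the median log2 fold change was 0.46 with upper-quartile scaling, 0.0943 after quantile normalization and 0.55 with equal reads. This median was -0.30 with a minimum mean of 50, 0.29 with DESeq2, and 0.27 to 0.31 with 1 library left out. For the pacemaker list it was -0.0469 after quantile normalization, 0.32 with equal reads and 0.00193 to 0.21 with 1 library left out. For the cell cycle list it was 0.28 with equal reads and -0.26 to 0.38 with 1 library left out. For the endoplasmic reticulum stress list it was 0.11 after quantile normalization, -0.0552 with a minimum mean of 50 and -0.0556 with DESeq2. With 1 library left out it was -0.10 to 0.0134. For the p53 list it was 0.0675 with no filter, 0.0788 with edgeR, 0.0648 with DESeq2 and 0.0361 to 0.10 with 1 library left out. Among groups chosen afterwards, quantile normalization gave 0.12 for cytosolic ribosomal proteins and 0.0269 for proteasome subunits, whose lower calls were also lost under 4 and 8 other alternatives, and glutathione S-transferases ran from -0.0241 to 0.0390 with 1 library left out; the cause was not tested.

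With the replicate block 2527 genes were higher and 2628 lower, 4937 of the 5164 calls were kept in the same direction, and 6 lists were higher and 7 lower. The labels do not say that a number marks a shared isolation; deviations of same-numbered libraries correlated at -0.00474, 0.151 and 0.0165, and a library correlated best with its own number for 2 of 3 numbers.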

Other observations

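The gene families in this and the next paragraph were chosen after the values were seen and tested on the same data, as were the tests below except the splits of the libraries. Some families share genes with the fixed lists, such as Krt18 with the epicardial and Col1a1 with the fibroblast list. Fixed lists share members too, such as Gja1 on the ventricular and intercalated disc lists. Results of overlapping lists and families are therefore not separate. Keratins and claudins were mostly higher in Tbx18. Of 8 tested keratins 6 rose and 0 fell, among them Krt18 from 290 ± 86.2 to 874 ± 53.6 and Krt17, at 0 in the GFP libraries and at 21.9 ± 7.11 in Tbx18, at least 6.36-fold higher (camera adjusted p = 0.00162; adjusted p = 0.275 with an estimated correlation). Of 7 claudins, tight junction proteins, 5 rose and 1 fell, with Cldn4 rising 6.76-fold (camera adjusted p = 0.0344; adjusted p = 0.447 with an estimated correlation), a call lost with upper-quartile, quantile and equal-read scaling and with DESeq2 (0.0161 to 0.189 over the alternatives). Of 23 collagen chains 16 rose and 2 fell, with Col1a1 rising 1.87-fold from 198103 ± 18663 and Col4a3 and Col4a4, chains of basement membrane, falling 2.86-fold each (camera adjusted p = 8.14e-06; adjusted p = 0.447 with an estimated correlation). Col1a2, the partner chain of Col1a1, was at 12.6 and 18.0 counts. The cause was not tested, and collagen values may depend on the annotation, which is not given in the sources used here. Of 6 laminins 5 fell, among them Lamc1 2.23-fold, and Lama1 rose from 3.04 to 27.4 (camera adjusted p = 0.0102; adjusted p = 0.447 with an estimated correlation).

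Of 66 mitochondrial ribosomal protein genes 41 fell and 0 rose, with a median log2 fold change of -0.40 (camera adjusted p = 1.03e-08, or 0.574 with an estimated correlation). With equal recovered reads their median was -0.14, where the median of all genes was 0.27, and 15 fell and 2 rose. With upper-quartile scaling 23 fell and 1 rose, and after quantile normalization 43 and 0. Cytosolic ribosomal protein genes had no direction that held across scalings. Of 75 tested, 11 fell and 0 rose, with a median of -0.16 (camera adjusted p = 0.00447; adjusted p = 0.693 with an estimated correlation). With upper-quartile scaling 2 rose and 0 fell (median 0.0125), after quantile normalization 14 and 0 (0.12), and with equal recovered reads 7 and 0 (0.10); 39 fell without GFP replicate 1, 4 without GFP replicate 2 or GFP replicate 3 and 2 without Tbx18 replicate 1 or Tbx18 replicate 3. The lower call was also lost without GFP replicate 2 and with DESeq2 (7.11e-06 to 0.403 over the alternatives). Of 19 MHC class I genes 6 rose and 0 fell, with a median of 0.48 (camera adjusted p = 0.00447, or 0.447 with an estimated correlation), and 3 were higher without Tbx18 replicate 3. With upper-quartile scaling 12 rose and 0 fell (median 0.65), with equal recovered reads 13 and 0 (0.74), and after quantile normalization 5 and 1 (0.22). The call of the MHC class I list was lost after quantile normalization (camera adjusted p from 0.000708 to 0.111 over the alternatives). Of 35 proteasome subunits 1 rose and 7 fell, with a median of -0.15 (camera adjusted p = 0.0389; adjusted p = 0.693 with an estimated correlation), but 4 rose and 1 fell with upper-quartile scaling (median 0.0253), 5 and 2 after quantile normalization (0.0269) and 7 and 0 with equal recovered reads (0.12). Of these genes 17 fell without GFP replicate 1 (median -0.23), 2 without Tbx18 replicate 3 (-0.0907), 3 without GFP replicate 2 (-0.0817) and 4 without GFP replicate 3, Tbx18 replicate 1 or Tbx18 replicate 2. The call was also lost with a minimum mean of 50, without GFP replicate 2, GFP replicate 3 or Tbx18 replicate 3, and with edgeR and DESeq2 (0.00304 to 0.798 over the alternatives). Semaphorins, histones, glutathione S-transferases and cholesterol synthesis genes were not called (camera adjusted p = 0.0625, 0.0625, 0.663 and 0.0961). Semaphorins were called higher without GFP replicate 1 (adjusted p = 0.0450) or Tbx18 replicate 2 (0.0399; 0.0399 to 0.298 over the alternatives), histones without GFP replicate 2 (0.0331; 0.0331 to 0.212), and cholesterol synthesis genes after quantile normalization (0.0321; 0.0321 to 0.241).

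The libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The study's own split was the 1 of the 10 that called most genes, 5164 against 0 at most for the others. It also called most lists, 13 against 7 to 12 for the others. Each other split mixed GFP and Tbx18 libraries on each side. The difference between the groups then counts as spread within a side, so the lack of gene calls there follows from the design. The mixed sides also keep part of that difference, so the lists that camera called there with the preset correlation do not measure chance. These counts therefore cannot decide whether the calls arose by chance, and no conclusion is drawn from them.

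The rise of all 25 interferon-response genes was weighed against scaling and against leukocytes. Under the other scalings the lowest median of the list was 1.74, which argues against scaling. Leukocyte markers had a median of 0.30 against 1.82 for interferon genes (two-sided permutation p = 0.00398, 100000 permutations). The permutations shuffled genes between the lists, so this p takes genes as independent and does not measure the spread between libraries. With 1 library left out the interferon median was at least 1.68, and the leukocyte median at most 0.62, without GFP replicate 2. This gap argues against more leukocytes as the whole source. Of the leukocyte markers Cd74, Mrc1, Csf1r and Cd68 were called higher and 0 lower. Lyz2, the most abundant of them, was at 631 and 519 counts, so a smaller contribution of leukocytes stays open. A difference in dose or preparation between the vectors, and an effect of Tbx18 itself, may each account for the rise and stay open, since the sources used here give no vector titre.

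Lower myocyte genes with higher stromal genes were weighed against a lower share of cardiomyocytes and against scaling. A lower share alone would lower genes expressed only in myocytes by like amounts. The log2 fold changes of the sarcomere genes had an SD 6.85 times their median standard error, so they did not change alike. Whether every member is expressed only in myocytes was not tested, so this spread cannot decide. Medians of other cell types do not decide it either. Their 95% bootstrap intervals resampled the genes of each list, so they do not measure the spread between libraries. Epicardial genes without Tbx18 had a median of 1.48 (0.85 to 1.68), fibroblast genes 0.86 (0.60 to 0.97) and smooth muscle genes 0.70 (0.30 to 1.33). Endothelial genes had 0.56 (0.35 to 1.00), Schwann genes 0.75 (0.12 to 1.06) and leukocyte genes 0.30 (0.12 to 0.65). The leukocyte median was 0.62 without GFP replicate 2. Under the other scalings the highest sarcomere median was -0.66 and the lowest fibroblast median 0.87. A shift of the cell mixture towards certain stromal cells and a change within myocytes may each contribute, and both stay open.

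Of 23 immediate early genes 14 fell and 1 rose, with a median of -0.79 (camera adjusted p = 0.00347; adjusted p = 0.582 with an estimated correlation), and Fos was at 399, 2143 and 3362 counts in GFP and 199, 197 and 226 in Tbx18. Under the other scalings the highest median was -0.53, which argues against scaling. Against GFP replicate 1 alone the median was -0.26; without that library it was -1.05, with 18 genes lower, and without GFP replicate 3 it was -0.55. A difference in handling among the GFP libraries and an effect of Tbx18 cannot be told apart, since the size depends on which GFP libraries are compared.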
